A study of Mus musculus with 9 samples.

How the data were processed

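Total RNA of microdissected anterior cingulate cortex from 9 mice was labelled and hybridised to 9 Affymetrix arrays, 3 per group (saline, ketamine, sleep deprivation), with tissue dissected from 1.34 to -0.5 mm relative to bregma, per the labels. The titles call the replicates biological. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1.1 and PLIER 2.0, an estimator that turns the probes of a probe set into 1 value. The deposited table holds 41345 probe sets in 9 columns as linear intensity values, each column mapped to its array by name. The background correction and the normalization between arrays that preceded it are not given in the sources used here. Array medians lay between 97.7 and 106.2. Values were used as deposited and were put on a log2 scale here, as log2(intensity + 16), so the log2 values are computed from the authors' intensities. The offset damps the change of dim probe sets. The number of arrays limits the precision. No batch or scan date was used here. Array numbers in the labels run in order by group, so hybridisation order and group cannot be told apart.

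Gene names came from the platform annotation, with symbols updated through gene identifiers to NCBI RefSeq names. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none in that annotation, and 23328 of those with 1 gene matched RefSeq. Probe sets with several genes were named for none. Where 1082 genes had several probe sets, the brightest on average was used, giving 22180 genes. No pair of arrays held identical values (0 pairs).

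Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with all 9 arrays in 1 fit, so that the groups shared 1 estimate of spread with 6 residual degrees of freedom, and with Benjamini-Hochberg adjustment over the genes tested at 0.05. No replicate number entered the fit. The 30 gene lists of textbook genes were prepared and tested with limma's camera at a preset correlation of 0.01, adjusted over 87 tests (29 lists in 3 comparisons), and beside it with an estimated correlation and with fry. fry asks whether a list's genes move on balance one way, or, in its mixed form, in either direction, and does not set the list against other genes. With an estimated correlation 0 of the 25 camera calls held, and fry called 0 lists (smallest adjusted p 0.319), while its mixed form reached an adjusted p of 0.00134. The list of cold-inducible RNA-binding genes had 2 measured members, under the minimum of 3, and was not tested. Some list members were not analysed here because no probe set with 1 gene named them, among them Per2, Csnk1d and Grin1. Gene lists, tests, the alternatives of the first plan and the rule for named genes were fixed before the data were examined.

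The rule named, per comparison, the 10 largest rises and 10 largest falls among genes past adjusted p 0.05 whose groups do not overlap, with free places filled by the smallest unadjusted p in that direction. As no gene passed, all of these places were filled by unadjusted p. It also allowed each core clock gene, list members past the threshold adjusted over the list alone or over all genes, up to 4 further members of each list, and 10 genes for the overlap of both comparisons with saline. Predicted genes and clones without a name were given with values where the rule named them, with no function described. Kl, given below, belongs to those list members.

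For genes shared by both comparisons with saline, 3 unchanged groups were simulated, the shared saline group among them. This was done in 100 draws with independent genes, and in 100 draws that regrouped the residuals of the 9 arrays. Regroupings that kept the 3 arrays of a group together were excluded, a choice made after the first draws were seen. The fit was tested on simulated data with 200 changed genes among 22180. In the simulated comparison of ketamine with saline it recovered 60% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1. It made 11, 0 and 15 false calls in ketamine against saline, sleep deprivation against saline and ketamine against sleep deprivation. The recovered shares hold for 200 genes changed at once, most of them by 1 or 2. So many changed genes ease the adjusted threshold, and recovery would be lower where few genes change. camera recovered the 1 list that was shifted and called 0 of 84 other tests when genes were independent. Alternatives covered normalization, centring, filters on dim genes, probe set choice, offsets of 1 and 64, limma-trend, array weights, thresholds, a replicate block and the removal of each array.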

Results

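Transcript levels in the anterior cingulate cortex of C57BL/6J mice, a common inbred laboratory strain, were measured on 9 Affymetrix arrays. The arrays fell into 3 groups of 3. Control mice received an intraperitoneal injection of saline at ZT5, that is 5 h after the lights came on. Ketamine, a blocker of the NMDA class of glutamate receptor that is used as an anaesthetic and, at low doses, as a fast-acting antidepressant, was injected at 3 mg/kg at the same time. The mice of the remaining group were kept awake from ZT0 to ZT12 by a bar rotating slowly through the cage, and the labels give no injection for them. All tissue was collected at ZT13. Median intensity per array lay between 97.7 and 106.2, and arrays of one group correlated at 0.976 to 0.991 across genes on the log2 scale. The number of arrays, 3 per group, limits the precision of every value below, and the median standard error of a difference between groups was 0.11 on the log2 scale. Changes are differences of log2(intensity + 16) ± SE from the limma fit with n = 3 arrays per group, and this offset understates the change of dim genes.

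The comparison of ketamine with saline asks what a single low dose leaves in the cortex 8 h later. Immediate-early genes, which neurons transcribe within minutes of activity, were lower after ketamine. Of 37 measured members, 36 had a lower mean than after saline and the median change was -0.26. The transcription factor genes Fos (probe set 17277387) and Junb (probe set 17511259) were lower by -0.42 ± 0.10 and -0.45 ± 0.09, and all 3 ketamine arrays lay below all 3 saline arrays for both. The MAP kinase phosphatase gene Dusp5 was at -0.43 ± 0.11 and Homer1, which encodes a postsynaptic scaffold protein, at -0.37 ± 0.11. The list was called by limma's camera with its preset correlation of 0.01 (adjusted p = 4.7e-17), and its adjusted p was 0.752 with an estimated correlation.

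Within that list 14 genes were lower and 0 higher when adjusted over the list alone, against 0 genes adjusted over all 22180 genes tested. The 14 were Arc, Dusp5, Dusp6, Egr2, Fos, Fosl2, Gadd45b, Homer1, Junb, Klf4, Nr4a1, Nr4a2, Ptgs2 and Sik1. Egr2, a zinc-finger transcription factor, had the largest of these values at -0.57 ± 0.16. Nr4a2 was at -0.44 ± 0.15, Sik1 at -0.42 ± 0.12 and Ptgs2, the inducible cyclooxygenase, at -0.40 ± 0.13. Arc, whose protein acts at the synapse, was at -0.32 ± 0.12.

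The core clock loop, the genes that form the circadian feedback circuit, shifted down against other genes, with 15 of 16 measured members lower and a median of -0.10 (camera adjusted p = 0.0128). Its adjusted p was 0.837 with an estimated correlation. No member passed adjusted over the list alone, where the count was 0 by limma against 1 at unadjusted p under 0.05. Ciart, a repressor of the loop, was at -0.23 ± 0.11, Bhlhe41 at -0.21 ± 0.09, Arntl at -0.11 ± 0.10, Clock at -0.046 ± 0.09, Cry1 at -0.15 ± 0.10 and Per1 at -0.056 ± 0.11, while Nr1d1 was at 0.12 ± 0.10. Clock output genes had a median of -0.094 with 12 of 16 lower (adjusted p = 0.0128, and adjusted p = 0.837 with an estimated correlation). After quantile normalization of the arrays the core loop's median was -0.032 and its adjusted p 0.079, and with the dimmest 33.3% of genes removed the adjusted p was 0.066. Without saline array 2 the core loop had adjusted p = 0.0549 and without ketamine array 3 a median of -0.057 (0.0498), while clock output had a median of -0.047 without saline array 1 (0.0294) and adjusted p = 0.05 without ketamine array 2, where its call was lost.

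Another 5 lists gave lower values after ketamine by the preset camera test, each with adjusted p = 0.837 with an estimated correlation. Of the lists called in this comparison, 8 were lower and 0 higher. Random lists matched to the immediate-early genes on mean expression had medians in a central range of -0.091 to -0.022. The clock lists and these 5 were not set against matched lists, so a general fall of bright genes was not separated from their changes. Oxidative phosphorylation had a median of -0.094 with 48 of 54 members lower (adjusted p = 5.7e-05), among them the complex I gene Ndufa2 at -0.30 ± 0.11. Heat shock genes had a median of -0.12, endothelial markers -0.11, meningeal fibroblast markers -0.15 and cytosolic ribosomal proteins -0.083, with adjusted p of 0.0115, 0.00978, 0.00978 and 0.018. Without saline array 1 all of these but oxidative phosphorylation had adjusted p of 0.102 or more, and oxidative phosphorylation had 0.0542. Endothelial markers (0.159) and heat shock genes (0.0549) also lost their calls without ketamine array 3, ribosomal proteins without ketamine array 2 (0.0733) and meningeal markers without ketamine array 1 (0.0825). Adjusted over each list alone the count was 0 in limma for all 5, with 5, 2, 0, 1 and 4 members lower at unadjusted p under 0.05 in the order named, beside 1 ribosomal protein gene higher.

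No gene passed the test over all genes between ketamine and saline. At adjusted p under 0.05 limma called 0 of 22180 genes, and 1013 had an unadjusted p under 0.05, 491 higher and 522 lower, where 1109 are due by chance. That count was 454 without saline array 2, 483 without ketamine array 3 and 1870 without ketamine array 1. limma with array weights, in which ketamine array 2 took a weight of 7.9, called 1438. The groups did not overlap for 14.4% of genes, where chance gives 10%. The smallest adjusted p, 0.87, belonged to Gm14459 (-0.79 ± 0.15). Other genes with small unadjusted p were Dio2, the deiodinase that activates thyroid hormone, at -0.47 ± 0.11, and the probe sets annotated to Mir212 (-0.47 ± 0.10), Mir1264 (-0.63 ± 0.14) and Mir128-1 (-0.51 ± 0.12). Probe sets for Olfr378 and Asb15 were at -0.64 ± 0.13 and -0.41 ± 0.10. In the upward direction the probe sets of Mir34a (0.51 ± 0.11), Mir107 (0.38 ± 0.10), Nxpe5 (0.48 ± 0.11), Psg21 (0.46 ± 0.12) and 6 odorant receptor genes came first. These were Olfr485, Olfr1336, Olfr830, Olfr164, Olfr672 and Olfr1420, with mean intensities from 8.71 to 57.9, below the array medians. A probe set annotated to a microRNA gene was not matched to either mature arm.

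**Figure D1:**
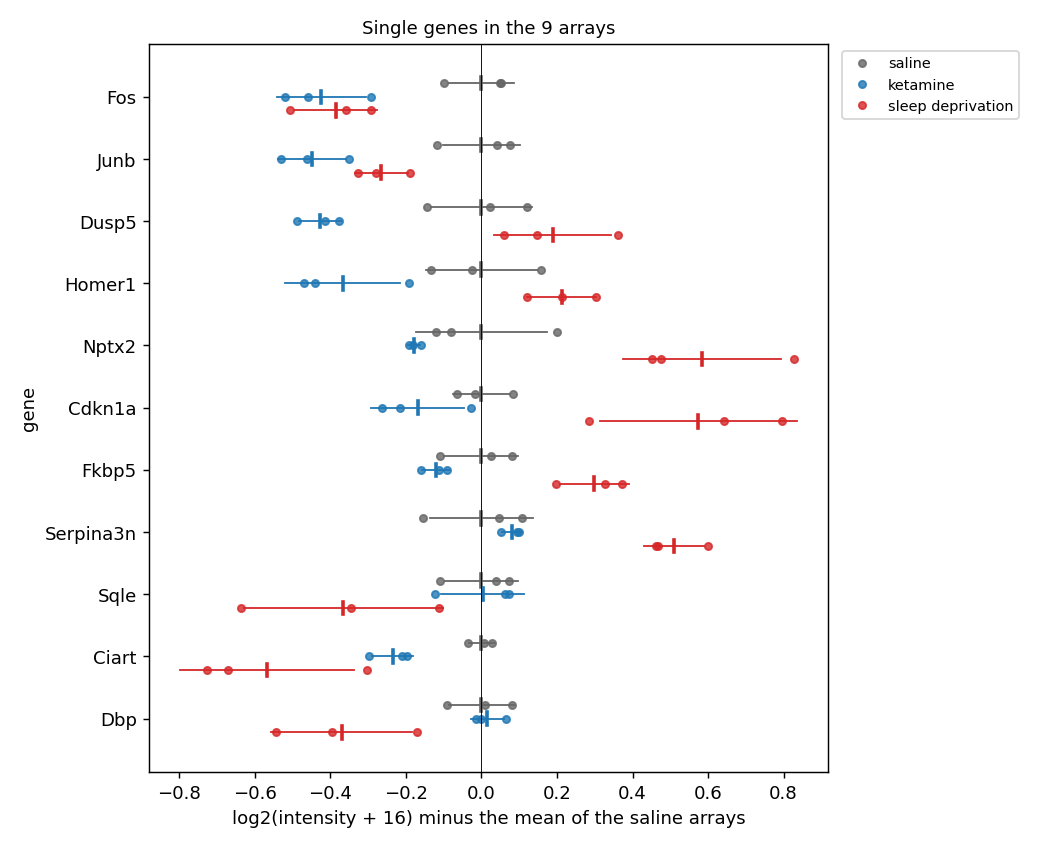
Level of 11 named genes in each of the 9 arrays, as log2(intensity + 16) minus the mean of the saline arrays on the horizontal axis, with 1 line per group; points are arrays, the short vertical bar is the group mean and the horizontal line is ± 1 SD (n = 3). Fos and Junb lie below saline in both other groups, while Nptx2, Cdkn1a and Serpina3n lie above saline in the sleep-deprived arrays and no gene shown passed adjusted over all genes.

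The comparison of sleep deprivation with saline asks what 12 h of enforced wakefulness across the light phase does to the same tissue. The labels give an injection for the saline mice alone of these 2 groups, so wakefulness and injection are not separated in any difference between them. Deprivation ended at ZT12 and tissue was taken at ZT13, so wakefulness and the interval after it are not separated either. Glucocorticoid-responsive genes, which are induced by the stress hormone corticosterone, were higher after sleep deprivation, 18 of 21 measured members, with a median of 0.12 (camera adjusted p = 1.4e-06, and adjusted p = 0.752 with an estimated correlation). Without sleep-deprived array 2 the median was 0.080 (camera adjusted p = 0.000972). The cell cycle inhibitor gene Cdkn1a (probe set 17335467) was higher by 0.57 ± 0.12, Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.30 ± 0.09, and the sulfotransferase gene Sult1a1 by 0.32 ± 0.10. Cholesterol synthesis genes were lower, 17 of 18 members, with a median of -0.16 (camera adjusted p = 1.4e-06, and adjusted p = 0.837 with an estimated correlation), which was -0.24 without that array. Oligodendrocyte markers had the same median, -0.16, with 15 of 16 lower. The squalene epoxidase gene Sqle was at -0.37 ± 0.12, Msmo1 at -0.32 ± 0.13, Fdps at -0.29 ± 0.13 and Hmgcs1, the HMG-CoA synthase, at -0.27 ± 0.10.

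Both calls used camera's preset correlation. Adjusted over the list alone, 4 glucocorticoid-responsive genes rose, namely Cdkn1a, Fkbp5, Sult1a1 and Lcn2. Lcn2, which encodes an iron-carrier-binding protein secreted in inflammation, was at 1.56 ± 0.51 with intensities of 566 and 503 in sleep-deprived arrays 1 and 3 but 70.2 in array 2, inside the saline range. For cholesterol synthesis the count adjusted over the list alone was 0 by limma, with 4 members at unadjusted p under 0.05, and the list median was near 0 in sleep-deprived array 2 (0.031) against -0.24 in each of the other sleep-deprived arrays.

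Of the core clock loop, Ciart (probe set 17407934; -0.57 ± 0.11) and Bhlhe41 (-0.33 ± 0.09) fell, adjusted over the list alone, and all 3 sleep-deprived arrays lay below all saline arrays for Ciart. Among clock output genes Dbp, a transcription factor driven by the loop, fell by 0.37 and Cdkn1a rose by 0.57, again adjusted over the list alone. Rorb was at -0.34 ± 0.13, Arntl at 0.18 ± 0.10, Npas2 at 0.13 ± 0.10, Clock at 0.10 ± 0.09, Per1 at 0.021 ± 0.11, Per3 at -0.052 ± 0.09 and Nr1d1 at -0.058 ± 0.10. As a list the loop was not called (median -0.055, 11 of 16 lower, camera adjusted p = 0.0578; adjusted p = 0.837 with an estimated correlation), while the mixed form of fry, for change in either direction, gave adjusted p = 0.00664 for the loop and 0.00663 for clock output. Without sleep-deprived array 2 the median was -0.10 and the adjusted p 0.00548.

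Immediate-early genes went both ways after sleep deprivation. Of 37 members 20 were higher and 17 lower, the median was 0.021, the mean was -0.00099, and camera gave adjusted p = 0.925, while the mixed form of fry, which asks for change in either direction, gave adjusted p = 0.00663. Adjusted over the list alone, Nptx2, a secreted pentraxin of excitatory synapses (0.59 ± 0.12), and the activin subunit gene Inhba (0.50 ± 0.15) rose, while Fos (-0.39 ± 0.10), Npas4 (-0.36 ± 0.11) and Btg2 (-0.42 ± 0.12) fell. Genes of BDNF signalling, mTOR and translation control had a median of 0.048 (adjusted p = 0.0336, and adjusted p = 0.837 with an estimated correlation), a call lost without saline array 1 (0.102), saline array 2 (0.0549), sleep-deprived array 1 (0.143) or sleep-deprived array 2 (0.578, median -0.0071), and Vgf, a neuropeptide precursor induced by BDNF, rose by 0.44 ± 0.10 adjusted over the list alone. The serotonin receptor gene Htr1b rose by 0.42 ± 0.11 within its receptor list in the same sense, while that list was not called (adjusted p = 0.729).

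By the preset camera test 3 lists of other cell types and 2 of general cell functions were called after sleep deprivation, and in these 5 lists limma passed 0 members adjusted over the list alone. Endothelial markers had a median of 0.10 with 15 of 17 members higher (adjusted p = 0.000857), including Vwf at 0.41 ± 0.12, and heat shock genes had a median of 0.051 (adjusted p = 0.00414), including Hspa1b at 0.42 ± 0.12. Oligodendrocyte markers had a median of -0.16 with 15 of 16 lower (adjusted p = 0.0115), oxidative phosphorylation a median of -0.046 (adjusted p = 0.0134) and choroid plexus and ependymal markers a median of -0.17 (adjusted p = 0.000165). All 5 had adjusted p = 0.837 or 0.839 with an estimated correlation. Ttr, the transthyretin gene of the choroid plexus, read 1624 and 8428 in saline arrays 1 and 2, 110 in saline array 3, and 89.5, 104 and 428 in the sleep-deprived arrays. The choroid list lost its call without saline array 2 (adjusted p = 0.0936) or sleep-deprived array 2 (adjusted p = 0.224), and oligodendrocyte markers lost theirs without saline array 2 (adjusted p = 0.355) or sleep-deprived array 1 (adjusted p = 0.326). Endothelial markers lost theirs without saline array 2 (adjusted p = 0.0525), heat shock genes without sleep-deprived array 2 (0.348), and oxidative phosphorylation without saline array 1 (0.598), sleep-deprived array 3 (0.106) or sleep-deprived array 1, where its median was 0.039 (0.374).

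No gene passed over all genes in this comparison either. limma called 0 of 22180 genes at adjusted p under 0.05, with 781 at unadjusted p under 0.05 (399 higher, 382 lower) where chance gives 1109, and limma-trend called 3, namely Mir29a, Sgsm1 and Mical2. The count at unadjusted p was 2079 without sleep-deprived array 3 and 1256 without sleep-deprived array 2. The groups did not overlap for 7.11% of genes, against 10% by chance. The probe set annotated to Mir29a (17465601) came closest, at 0.96 ± 0.12 and adjusted p = 0.0556, with a low mean intensity of 35.1. Serinc2 was at 0.59 ± 0.10, the Rab GTPase regulator Sgsm1 at 0.57 ± 0.10, the transporter gene Slc4a11 at 0.53 ± 0.10, and Serpina3n, an acute-phase serine protease inhibitor, at 0.51 ± 0.10. Mical2, an actin-oxidizing enzyme, was at 0.41 ± 0.09, Krtap19-9b at 0.55 ± 0.11 and Mir582 at 0.52 ± 0.11. Lower values were found for Sytl2 (-0.47 ± 0.10), Spin4 (-0.45 ± 0.11), Shd (-0.34 ± 0.08), Gm12371 (-0.68 ± 0.17), Kir3dl1 (-0.45 ± 0.11), 6330415G19Rik (-0.33 ± 0.08), Olfr1084 (-0.44 ± 0.10) and Vmn1r173 (-0.50 ± 0.12), the last 2 at mean intensities of 7.95 and 3.40.

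The direct comparison of ketamine with sleep deprivation asks where the 2 treatments differ, with an injection given in the labels for the ketamine mice alone. For the sleep-deprived mice the interval from ZT12 to ZT13 is part of any difference here too. Immediate-early genes were again lower on the ketamine side, 32 of 37 members, with a median of -0.22. Nptx2 (probe set 17444498) was lower by -0.76 ± 0.12, Inhba by -0.65 ± 0.15, Dusp5 by -0.62 ± 0.11, Homer1 by -0.58 ± 0.11, Ptgs2 by -0.58 ± 0.13 and Bdnf, the brain-derived neurotrophic factor gene, by -0.52 ± 0.12. Cdkn1a was at -0.74 ± 0.12, Fkbp5 at -0.42 ± 0.09 and the inducible chaperone gene Hspa1b at -0.58 ± 0.12. Sqle and Hmgcs1 were at 0.37 ± 0.12 and 0.29 ± 0.10 in the direction of ketamine, and limma passed 0 cholesterol synthesis genes adjusted over the list alone. Oligodendrocyte markers had a median of 0.20, beside 0.16 for that list. Relative to saline, cholesterol genes stood at 0.012, 0.039 and -0.13 in ketamine arrays 1 to 3, and oligodendrocyte markers at 0.030, 0.44 and -0.27. In sleep-deprived arrays 1 to 3 cholesterol genes stood at -0.24, 0.031 and -0.24, and oligodendrocyte markers at -0.25, -0.064 and -0.041. The 2 lists thus did not match in size array by array.

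By the preset camera test 9 lists differed. Lists were not set against others matched on mean expression here or between sleep deprivation and saline. A general shift of bright genes was thus not separated from the calls in these 2 comparisons. Immediate-early genes (adjusted p = 4.2e-11), endothelial markers (2.2e-06), heat shock genes (1.7e-05), glucocorticoid-responsive genes (2.0e-05), the unfolded protein response (0.00414) and BDNF, mTOR and translation control (0.0122) were lower after ketamine. Cholesterol synthesis (0.00164), oligodendrocyte markers (0.00997) and choroid plexus markers (0.0357) were higher. The glucocorticoid list had adjusted p = 0.752 with an estimated correlation and the other 8 adjusted p = 0.837 with an estimated correlation. Adjusted over each list alone, 14 immediate-early genes were lower, beside 4 heat shock genes (Hspa1b, Hsph1, Chordc1 and Dnajb5), 5 glucocorticoid-responsive genes (Cdkn1a, Fkbp5, Il1r1, Sult1a1 and Lcn2), Vgf and Bdnf in the BDNF list and Vwf among endothelial markers. Dbp was higher after ketamine by 0.39 ± 0.10 and the microglia genes C1qb and Fcrls lower by -0.36 ± 0.10 and -0.35 ± 0.10, adjusted over their lists alone. The core clock loop was not called (median -0.056, camera adjusted p = 0.729), while the mixed form of fry gave adjusted p = 0.0224 for the loop and 0.00663 for clock output. Oligodendrocyte markers had a median of 0.20, which was 0.0086 without ketamine array 2, where their median stood 0.44 above saline. Without sleep-deprived array 2 the adjusted p was 0.483 for choroid plexus markers, 0.33 for the unfolded protein response and 0.137 for the BDNF list, and it was 0.231 for cholesterol synthesis without sleep-deprived array 3 and 0.154 for oligodendrocyte markers without sleep-deprived array 1.

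limma called 0 of 22180 genes at adjusted p under 0.05 between ketamine and sleep deprivation, while 2102 had an unadjusted p under 0.05, 1132 higher and 970 lower, where chance gives 1109. limma-trend called 15 genes, among them Nptx2, Cdkn1a, Dusp5, Homer1, Vgf, Sgsm1, Serinc2, Slc4a11 and Mical2. The smallest adjusted p was 0.172, shared by Nptx2, Slc4a11 (-0.61 ± 0.10), Cdkn1a, Sgsm1 (-0.57 ± 0.10), Dusp5 and Olfr45 (0.69 ± 0.12). Lower after ketamine were also Gpx2 (-0.84 ± 0.15, at a low mean intensity of 16.2), Serinc2 (-0.55 ± 0.10) and the probe sets of Mir582 (-0.62 ± 0.11) and Mir29a (-0.68 ± 0.12). Higher were Olfr156, Olfr98, Neurog1, Csl, Prl8a8, Smok2a, Tas2r134, Slc39a4 and Cyp2c37, at mean intensities between 22.3 and 85.5, which lie below the array medians. The groups did not overlap for 10.1% of genes, against 10% by chance. Without sleep-deprived array 3 the count at adjusted p under 0.05 was 214 and at unadjusted p under 0.05 it was 4762, and without ketamine array 3 the count at unadjusted p under 0.05 was 1109.

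**Figure D2:**
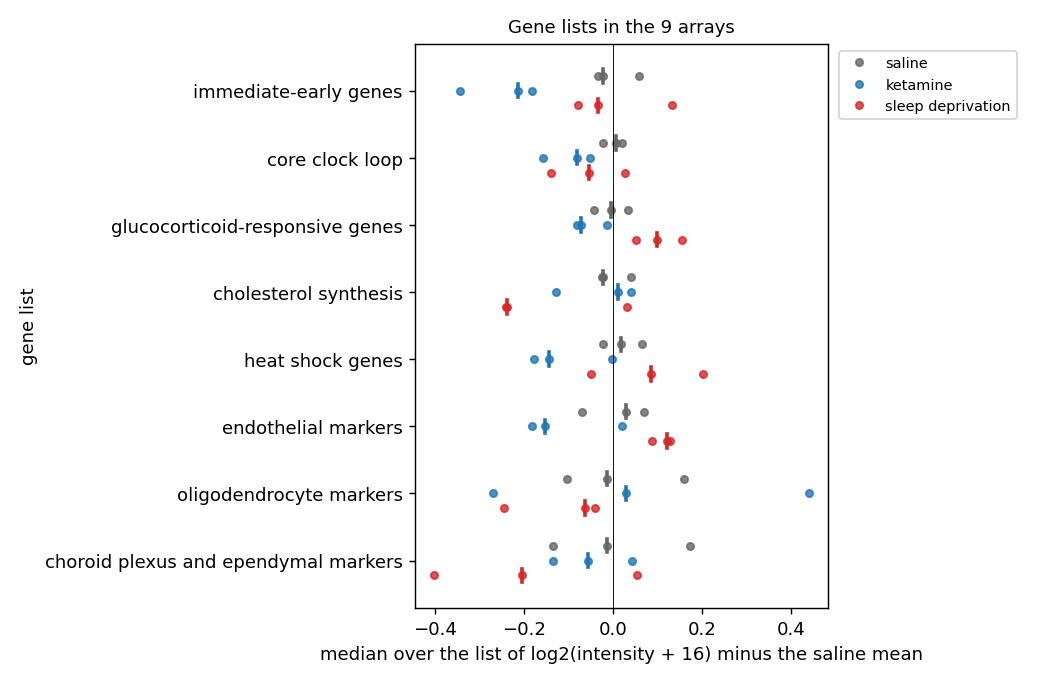
Median over each gene list of log2(intensity + 16) minus the saline mean of each gene, on the horizontal axis, for 8 lists in the 9 arrays; points are arrays and the short bar is the median of the group's 3 arrays. The 3 ketamine arrays lie between -0.34 and -0.18 for immediate-early genes, below all saline and sleep-deprived arrays, and oligodendrocyte markers spread from -0.27 to 0.44 among ketamine arrays.

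Whether both treatments moved the same genes away from saline was measured over the 22180 genes. At unadjusted p under 0.05 in both comparisons, 36 genes were higher and 34 lower in both, 70 in all, and 4 went in opposite directions. Fos was lower in both, by -0.42 ± 0.10 after ketamine and -0.39 ± 0.10 after sleep deprivation, as was Junb by -0.45 ± 0.09 and -0.27 ± 0.09. Sgcz, a sarcoglycan gene, was at -0.40 ± 0.13 and -0.39 ± 0.13, and Mir34a at 0.51 ± 0.11 and 0.35 ± 0.11. Vmn1r173, Kir3dl1, Oog1 and Mir3098 were lower and Speer5-ps1 and Olfr194 higher in both, all at mean intensities from 3.40 to 42.4.

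Independent lists of these sizes would share 17.8 genes, but both comparisons use the same 3 saline arrays. Unchanged groups simulated with independent genes shared 230 genes in the same direction on average, with a central range of 203 to 260 over 100 draws. Regrouping the residuals of the 9 arrays, which keeps the correlation between genes, gave 261 on average with a central range of 11.4 to 1567. The 70 found lie below the first range and inside the second. Across genes, which are not independent replicates, the fold changes correlated at r = 0.19, where simulated independent genes gave 0.49 to 0.52 and regrouped residuals 0.12 to 0.80. Their covariance was 0.00288, where these gave 0.00662 to 0.00721 and 0.00175 to 0.0218. The saline arrays could not be divided into parts of at least 2 arrays. The excess of 70 over 17.8 may come from the shared controls. Both simulations gave saline the same spread as the treated groups. Array weights, which are lower for arrays with more scatter, were 1.02 to 2.08 for saline and 0.348 to 0.918 for sleep deprivation. For ketamine they were 0.655, 7.93 and 0.467. Less scatter in saline would give less overlap. The simulated values thus cannot decide how much of the 70 comes from shared controls. Without sleep-deprived array 2 the count was 204 and r was 0.41. In turn r was 0.31 without saline array 1, 0.34 without saline array 3, 0.10 without ketamine array 1 and -0.093 without sleep-deprived array 3.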

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

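Dropping ketamine array 3 with sleep-deprived array 2, quantile normalization with limma-trend, and limma-trend after removing the dimmest 33.3% or 66.7% of genes, with and without quantile normalization, were chosen after seeing the data; the other alternatives were planned. Over the alternatives, named genes gave 9735 values. Of these, 9504 kept their side of the threshold without a counted reversal, 223 came to pass and 8 reversed. Lists gave 2007 values, of which 1807 stayed likewise, 140 lost and 58 gained a call and 2 reversed. A change of sign counted as a reversal only for genes whose main change exceeded its SE and for lists called in the main fit. Other changes of sign are not among the reversals. No gene passed in the main fit, so none could lose a pass. The cause was not tested unless named. Immediate-early genes kept their call in both comparisons with ketamine, and cholesterol and glucocorticoid genes theirs in sleep deprivation against saline, in every alternative but the estimated correlation (adjusted p = 0.752, 0.837, 0.837 and 0.752, medians -0.26, -0.22, -0.16 and 0.12) and fry (adjusted p = 0.319, 0.319, 0.706 and 0.319); leaving out single arrays gave medians of -0.29 to -0.21, -0.26 to -0.17, -0.24 to -0.11 and 0.080 to 0.17. With either of those tests 0 lists were called in each comparison. Lists called against saline for ketamine numbered 5 with every probe set tested, 2 with quantile normalization, limma-trend and the dimmest 33.3% removed, 3 and 1 with 66.7% removed without and with quantile normalization, and 3 (without saline array 1) to 10 (without saline array 2) with single arrays left out. For sleep deprivation they numbered 4 with 66.7% removed and quantile normalization and 5 (without saline array 2) to 10 without single arrays, and for ketamine against sleep deprivation 5 and 5 with 66.7% removed.

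The core clock loop lost its call after ketamine with quantile normalization, alone or with limma-trend (median -0.032, adjusted p 0.079), with the dimmest 33.3% removed, alone or with limma-trend (-0.10, 0.066), with quantile normalization too (-0.031, 0.224), with 66.7% removed (-0.089, 0.468, and -0.025, 0.428 when quantile normalized), by fry (-0.10, 0.706), with an estimated correlation (-0.10, 0.837) and without saline array 2 (-0.11, 0.0549), within -0.12 to -0.057 without single arrays. After sleep deprivation it gained one with quantile normalization, alone or with limma-trend (-0.055, 0.0239), with the dimmest 33.3% removed, alone or with limma-trend (-0.055, 0.0348), with quantile normalization too (-0.0595, 0.0251), with 66.7% removed (-0.052, 0.0447), with an offset of 64 (-0.047, 0.0214), without saline array 1 (-0.066, 0.0218), without sleep-deprived array 2 (-0.10, 0.00548) and without the 2 arrays named first (-0.10, 0.00711), within -0.10 to -0.021 without single arrays.

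Genes past adjusted p 0.05 numbered, for ketamine against saline, 1438 with array weights, 1013 at unadjusted p, 8 of these with a fold of at least 1.5, and 0 without any single array. For sleep deprivation against saline they numbered 1 with median centring, 3 with limma-trend, 1 without the 2 arrays, 12 with quantile normalization and limma-trend, 2 and 15 with the dimmest 33.3% removed without and with quantile normalization, 8 and 15 with 66.7% removed, 1 at adjusted p under 0.10, 781 at unadjusted p, 19 of these with the fold, and 0 to 4 (without sleep-deprived array 2) without single arrays. For ketamine against sleep deprivation they numbered 5 with the dimmest 33.3% removed, 15 with limma-trend, 42 with array weights, 14 with an offset of 64, 1 without the 2 arrays, 10 with quantile normalization and limma-trend, 14 and 14 with limma-trend and 33.3% removed, 28 and 14 with 66.7% removed, 2102 at unadjusted p, 55 of these with the fold, and 0 to 214 (without sleep-deprived array 3) without single arrays.

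Genes at unadjusted p under 0.05 numbered, for ketamine against saline, 2057 with every probe set, 1865 in a fit of the 2 groups, 6087 with array weights, 448 and 438 with 66.7% removed, and 454 (without saline array 2) to 1870 (without ketamine array 1). For sleep deprivation they numbered 1472 with every probe set, 1374 with weights, 1558 without the 2 arrays, 375 with 66.7% removed, and 571 (without saline array 2) to 2079 (without sleep-deprived array 3). For ketamine against sleep deprivation they numbered 3674 with every probe set, 4150 with weights, 1394 without the 2 arrays, 749 and 784 with 66.7% removed, and 1109 (without ketamine array 3) to 4762 (without sleep-deprived array 3); fewer or more genes tested account for part of these shifts. Genes shared in direction by both comparisons with saline numbered 130 with quantile normalization, 132 with limma-trend too, 108 with the dimmest 33.3% removed as well, 41 with 33.3% removed alone, 42 with 66.7% removed, 199 with every probe set, 316 with weights, 134 without the 2 arrays and 52 (without ketamine array 2) to 204 (without sleep-deprived array 2). The correlation of fold changes was 0.33 without the 2 arrays, 0.36 and 0.37 with 66.7% removed, and -0.093 (without sleep-deprived array 3, reversed) to 0.41.

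Reversed in ketamine against sleep deprivation were Ccn2 with the mean over probe sets (0.043), oligodendrocyte markers without ketamine array 2 (0.0086, by the direction of the test, within 0.0086 to 0.40 without single arrays) and, without the 2 arrays, Atp5k (0.0022), Ngp (-0.052), Otx2 (-0.013), Plekhg1 (0.040) and Slc17a6 (0.060). S100a8 (0.054, within -0.49 to 0.054 without single arrays) and oxidative phosphorylation (0.039, within -0.11 to 0.039) reversed in sleep deprivation against saline without sleep-deprived array 1, and Sox10 (-0.025, within -0.025 to 0.31) in ketamine against saline without ketamine array 2. With a replicate block the counts at unadjusted p under 0.05 were 1254, 887 and 2457 for ketamine and sleep deprivation against saline and against each other, and no call changed. In their deviations from the group mean, same-numbered arrays correlated at -0.20 to 0.44, above 0.1 in 2 of 9 pairs. Differently numbered arrays correlated at -0.51 to 0.54. For saline with ketamine, same-numbered pairs stood at 0.051, 0.12 and 0.077 and the others at -0.11 to 0.029. With 3 arrays per group these values cannot decide whether the numbers pair the samples. Array weights rest on 3 arrays per group and gave ketamine array 2 a weight of 7.9. Probe sets near the floor of signal limit the odorant receptor, microRNA and Gpx2 values.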

Other observations

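The tests of the choroid plexus pattern, of the counts between ketamine and sleep deprivation, of the neuronal share and of single arrays behind the immediate-early genes were chosen only after the results were seen, and the comparison with matched random lists and the other groupings of arrays were set before.

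By camera with its preset correlation, genes of synaptic machinery and markers of neurons and glia other than oligodendrocytes showed no call in any of the 3 comparisons. The mixed form of fry, which asks for change in either direction, called excitatory neuron and layer markers after sleep deprivation (adjusted p = 0.00663) and microglia markers between ketamine and sleep deprivation (adjusted p = 0.00134). Adjusted over the list alone, 1 synaptic gene (Homer1), 1 interneuron gene and 2 microglia genes (C1qb and Fcrls) passed between ketamine and sleep deprivation. Between ketamine and saline the median change was -0.023 for synaptic scaffold and vesicle genes (camera adjusted p = 0.564), -0.012 for excitatory neuron and layer markers (0.596), -0.083 for interneuron markers (0.143), -0.059 for astrocyte markers (0.27), -0.049 for microglia markers (0.27) and 0.044 for oligodendrocyte precursors (0.192). Glutamate receptor genes, the family that holds ketamine's target, had a median of -0.063 (0.31), and GABA genes -0.051 (0.113). Monoamine, acetylcholine, adenosine and orexin receptors had a median of -0.037 while their test pointed up (0.867). Interferon response genes were at 0.058 (0.141) and inflammatory mediators at 0.061 (0.141). Pericyte and smooth muscle markers (-0.052, 0.536), striatal neuron markers (-0.050, 0.613), septum and thalamus markers (-0.069, 0.193) and blood cell markers (0.096, 0.202) were not called either. Single members stood apart, such as the calretinin gene Calb2 at -0.40 ± 0.13 and the vasoactive intestinal peptide gene Vip at -0.28 ± 0.11 after ketamine, neither of which passed adjusted over its list alone in that comparison. Vip was lower after ketamine than after sleep deprivation by -0.41 ± 0.11, which passed adjusted over the interneuron list alone. After sleep deprivation the layer markers Etv1 (-0.31 ± 0.09) and Calb1 (-0.30 ± 0.11) and the metabotropic receptor gene Grm2 (-0.23 ± 0.09) had low values that did not pass.

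Lower immediate-early genes after ketamine formed a pattern with a median of -0.26 over 37 genes. Of 10000 random lists of the same size matched on mean expression, 0% had a median as low, and 95% of them lay between -0.091 and -0.022, which argues against a compression of bright genes on the ketamine arrays. Synaptic and excitatory neuron genes outside the list had a median of -0.012 (95% bootstrap interval over genes -0.051 to 0.022), above -0.13. Interneuron markers, glutamate receptor genes and GABA genes were lower, with medians of -0.083, -0.063 and -0.051, which also lie above -0.13. These medians argue against a smaller neuronal share as the main source of the fall. The interval is over genes and does not measure the spread between arrays. Leaving out any 1 of the 6 arrays left the list median at -0.21 or lower. A lasting effect of ketamine on activity-dependent transcription may account for it, as a hypothesis drawn from these same arrays and not tested here, with injection order and handling left open.

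Choroid plexus and ependymal markers were lower after sleep deprivation, with a mean change of -0.39. Without saline array 2, where Ttr read 8428 and the anti-ageing gene Kl read 587 against 113 to 140 in the other arrays, the mean was -0.17 and the adjusted p 0.0936, so choroid plexus tissue in that dissection may account for much of the pattern. The call was also lost without sleep-deprived array 2, whose list median was -0.40, against -0.21 and 0.054 in sleep-deprived arrays 1 and 3. The pattern thus does not rest on that saline dissection alone. Of the 3 sleep-deprived arrays, 1 lay above the lowest saline array in Ttr, so a fall in every sleep-deprived array is not what the values show. Saline array 1 read 1624 in Ttr as well. Without saline array 2 Ttr was still at -1.35, beside the list mean of -0.17 and a list median of -0.090. A smaller effect of sleep deprivation itself stays open and was not separated from the high Ttr of saline array 1.

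More genes had an unadjusted p under 0.05 between ketamine and sleep deprivation (2102) than in either comparison with saline (1013 and 781). That order turned round with array weights (4150 against 6087 for ketamine against saline) and in fits of 2 groups at a time (1491 against 1865). After quantile normalization the count between ketamine and sleep deprivation was 2201. That step removes differences of spread within groups as well as between them, so a similar count cannot exclude unequal spread between arrays. Without ketamine array 3 and sleep-deprived array 2, the ends of the first principal component, the same count was 1394, against 1109 by chance. For sleep deprivation with saline it then was 1558, so the order did not hold without those 2 arrays. Fewer arrays weaken a test, yet this last count rose from 781, so lost power was not shown to cause the fall to 1394. The share of those 2 arrays cannot be told apart from a treatment difference. That component held 38.2% of the variance and followed the interquartile range of log2 values over the 9 arrays (Pearson r = -0.986, exact permutation p = 0.000132; Spearman rho = -0.95, exact permutation p = 0.000353; 1 relation computed), with r = -0.928 without those same 2 arrays. Opposite treatment effects may add to the count, which was not separated here.

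Other groupings of the same 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. For ketamine against saline the real grouping gave 1013 genes at unadjusted p under 0.05 and the highest other 923, so 1 of the 10 gave as many. For sleep deprivation against saline the real value was 781 and the highest other 2319, with 8 of the 10 as large, and for ketamine against sleep deprivation 2102 and 5393, with 5 of the 10 as large. The 5393 came from sleep-deprived arrays 1 and 2 with ketamine array 1 set against the rest, which points to a structure among these arrays beside treatment. On the first principal component these 3 arrays stood at -8.8, -26.7 and -1.6. Sleep-deprived array 3 stood at 10.5 and ketamine arrays 2 and 3 at 8.9 and 26.2. That grouping thus followed the component that tracked the interquartile range of log2 values. What set that range was not tested. Lists called by camera with its preset correlation numbered 8 with a highest other of 8 (2 of the 10 as large), 8 with a highest other of 12 (5 of the 10) and 9 with a highest other of 10 (3 of the 10) in the same order. The size of the immediate-early median between ketamine and saline was 0.26 in the real grouping and at most 0.14 in the others.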
